A study of Rattus norvegicus with 3 samples.

How the data were processed

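HA-TET2 CUT&Tag was measured in 3 samples of rat aortic SMC, 2 Control and 1 Myocd-LSD1, grouped by the cell line and title in the labels. Per the submitters' processing notes, Bowtie2, deepTools, MACS2 and ChIPseeker were used and the genome build was rn6; versions and settings are not given in the sources used here. The deposited files were 2 lists of narrow peaks, 1 per group, annotated with the nearest gene. Both Control samples name the same list, and every peak identifier within a list names 1 alignment; whether the Control reads were pooled is not given in the sources used here. No input, IgG or untransduced sample was used here.

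Each peak has a position, an annotation and values that the authors' peak caller gave. The deposited fold enrichment is a ratio, and what it is relative to is not given in the sources used here. It was used to describe and rank peaks within its own list. It also served, together with the p-value, to recover pile-ups and local background as described below. The deposited −log10 p-values and −log10 q-values are per peak; the lowest −log10 q-value was 1.32 in Control and 1.31 in Myocd-LSD1, a q-value threshold of 0.05. The deposited score is the −log10 q-value multiplied by 10 and truncated, and was not used further. The summit offset and the distance to the start site are in bp in the deposited lists. The start column counts from 0, as tested against the deposited distances, and starts are given here counted from 1. In both lists the header line holds the name of peak 1 and no values of it, so that this peak could not be used; 45 peak numbers are missing in Control and 23 in Myocd-LSD1. Annotation classes and gene assignments are those of the authors, with promoters spanning 3 kb to each side of a start site. Exon numbers are theirs too and need not run from the start site. For Ezr, a Control peak in exon 1 of 13 lay 42341 bp from it. A contractile gene of the fixed list is not reported by name here. A peak assigned to a gene can lie in another gene, and where it does this is said. Conversely, the Tet2 exon peaks described below lie in Tet2 but were not assigned to it. The DNA methylation list therefore counts Tet2 with 1 Control peak and 0 Myocd-LSD1 peaks.

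Peaks of the lists were compared by an overlap of at least 1 bp, beside 1000 random circular shifts within each chromosome. Shares have exact binomial (Clopper-Pearson) intervals at 95%, which cover counting error only, since peaks and genes are not replicates. Fragments from amplified libraries are not independent molecules, although the Poisson and thinning steps below treat them so. With 1 list per group there was no test across replicates, and no p-value was made from peaks. A gene list was placed among 10000 random lists of the same size, drawn from all genes with a Control promoter peak and matched on the decile of the strongest fold. The draws permute list membership within these deciles. The two-sided rank p describes these libraries, not the conditions, and was adjusted by the Benjamini-Hochberg method over the lists with at least 5 such genes. The 16 gene lists (smooth muscle contractile genes, smooth muscle transcription factors, early SRF targets, phenotypic modulation, DNA methylation, H3K4 methylation, cell cycle, housekeeping, TGF-β and BMP, actin cytoskeleton, homeobox and fate regulators, and markers of endothelium, macrophages, neurons, hepatocytes and other muscle) were fixed before the data were examined. So was the rule for named genes. It allows every contractile gene or smooth muscle transcription factor with a peak, up to 4 members of each other list in order of fold, the 10 highest promoter peaks found in each list alone with no promoter peak of that gene in the other, and the 10 promoter peaks of highest mean rank in both. It takes assembled chromosomes and passes over provisional symbols. The genes named for their exon peaks, and Tdg and Tet2, were chosen after their values were seen.

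The number of fragments behind each peak was recovered, a step chosen after seeing the data. It takes the fold as (k + 1)/(λ + 1) for a pile-up k and a local background λ, and the p-value as the Poisson chance of more than k fragments, as MACS2 computes them, so that both values together fix a whole number k. A solution within the rounding of the deposited values, or else a nearest whole number with a misfit under 0.1 of the next one, was found for 25496 Control peaks (99.9%) and 9520 Myocd-LSD1 peaks. The lowest λ of a list outside the mitochondrial sequence was taken as its background coverage. For the expected share, each Control pile-up was thinned by the ratio of the background coverages (0.362), and the binomial chance of reaching the weakest Myocd-LSD1 call (−log10 p of 4.22) was averaged. Pile-ups are heights at a peak's summit, not read totals, and the mitochondrial sequence was left out of these shares.

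The steps were tested on simulated data. Overlaps differed from bedtools in 0 intervals, and of 3089 simulated peaks every pile-up with a single solution was the one simulated. Pile-ups drawn by the same thinning rule gave 0.998 of the expected share with no site lost and 0.506 with 50% of sites lost. These draws used the call limit of the expectation itself, so they check its arithmetic alone. Selection of Control peaks for high counts and a new round of peak calling were not simulated. Among random lists of 20 genes 3% had a rank p under 0.05, and among those with 75% of calls removed 85.5%. The alternatives were a stricter threshold (the median −log10 q of Control, 4.40, for both lists), equal numbers of peaks, assembled chromosomes alone, other overlap rules, other definitions of a gene's peaks, other matching of random lists and other deciles. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. No genome sequence was used here, so GC content and binding motifs were not examined.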

Results

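HA-tagged TET2, a dioxygenase that oxidises 5-methylcytosine in DNA, was expressed from an adenovirus for 24 h in rat aortic smooth muscle cells (SMC), and its sites were mapped by CUT&Tag with an antibody against the HA tag, from 500000 cells per assay. In CUT&Tag, a transposase held by the antibody cuts and tags the DNA around the bound protein. There were 3 samples, 2 from control SMC (Control replicates 1 and 2) and 1 from a line called Myocd-LSD1 (replicate 1), named for myocardin, the coactivator of SRF that drives the smooth muscle programme, and LSD1, a demethylase of histone H3 lysine 4. The comparison asked where TET2 was found in Myocd-LSD1 SMC and in control SMC. Each group was represented by 1 list of called peaks, so no value below has a replicate error and no p-value was taken between the conditions. Intervals are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only. The lists give no read totals, and depth was read from the peaks themselves. The uniform background under the peaks came to 0.175 fragments in Control and 0.0633 in Myocd-LSD1, a ratio of 2.77. A Control peak rested on a median of 7 overlapping fragments (interquartile range 5 to 12) and a Myocd-LSD1 peak on 5 (3 to 7), and 6.48% of Control peaks but 30.2% of Myocd-LSD1 peaks had 3 fragments or fewer.

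Fewer HA-TET2 peaks were called in Myocd-LSD1 SMC than in control SMC, and those that were called lay closer to transcription start sites. The Control list held 25521 peaks over 9.52 Mb and the Myocd-LSD1 list 9523 peaks over 2.78 Mb, a ratio of 2.68 in number and 3.42 in covered length. The median peak was 315 bp wide in Control and 250 bp in Myocd-LSD1. The Control peaks were assigned to 13312 genes and the Myocd-LSD1 peaks to 7579. The ratio of peak numbers was 4.28 when both lists were held to the same stricter significance minimum. Because the background coverage differed by about as much as the peak numbers, the number of peaks alone does not separate fewer bound sites from a thinner library.

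Most Myocd-LSD1 peaks lay on Control peaks, while most Control peaks had no counterpart. Of the Myocd-LSD1 peaks, 5656 shared at least 1 bp with a Control peak (59.4%, interval 58.4 to 60.4), and of the Control peaks 5623 shared at least 1 bp with a Myocd-LSD1 peak (22.0%, 21.5 to 22.5). Over 1000 random circular shifts of the other list the mean overlap was 0.688% and 0.255%, and no shift exceeded 1.06% and 0.357%. A Control peak that overlaps a Myocd-LSD1 peak is called met below. Met peaks were the stronger ones in both lists, with a median deposited fold enrichment of 6.69 against 4.98 for unmet peaks in Control and 5.54 against 3.63 in Myocd-LSD1. In the lowest decile of Control peaks by fold 7.05% were met, and in the highest 57.5%. All 193 Myocd-LSD1 peaks with more than 20 overlapping fragments had a Control peak (lower bound 98.1%), and of the 1672 with 2 fragments 9.57% had one. With the Control list shortened to its 9523 most significant peaks, 38.7% of Control and 39.1% of Myocd-LSD1 peaks overlapped, and with a reciprocal overlap of 50% the shares were 14.4% and 38.6%.

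The classes of sites were unequally represented. Promoters, taken as 3 kb to each side of a start site, held 30.3% of Control peaks (29.7 to 30.8) and 44.4% of Myocd-LSD1 peaks (43.4 to 45.4), and the part within 1 kb held 23.4% and 39.6%. Exons outside promoters held 2723 Control peaks (10.7%, 10.3 to 11.1) and 333 Myocd-LSD1 peaks (3.50%, 3.14 to 3.89), a ratio in number of 8.18, against 1.58 for promoters within 1 kb, 3.37 for introns, 2.69 for distal intergenic sites and 7.89 and 5.53 for the few peaks in 5′ and 3′ untranslated regions. Introns held 29.8% and 23.7% of the peaks, and distal intergenic sites 26.9% and 26.8%. The median distance to the nearest start site was 11082 bp in Control and 5980 bp in Myocd-LSD1, and 11.7% and 21.1% of peaks lay across a start site.

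To set these shares beside what the thinner library could give, each Control peak was thinned to the Myocd-LSD1 background coverage and its chance of still being called was computed. The expectation depends on the ratio used for thinning, and selection of Control peaks for high counts there tends to make it too high. Over all peaks 22.0% were met and 46.9% expected. For promoter peaks within 1 kb of a start site the observed share was 44.4% and the expected share 49.1%, a ratio of 0.904 (0.878 to 0.930). The ratio turned to 1.18 (1.15 to 1.22) when thinning followed the pile-ups of strong shared peaks. These are met Control peaks of at least 30 fragments, so that scale is not independent of the share that it is set against. The ratios of the exon, intron and distal intergenic classes stayed under 1 on both scales. Between 1 and 2 kb from the start site the ratio was 0.338, and between 2 and 3 kb it was 0.300. For exon peaks 8.53% were met and 48.1% expected, a ratio of 0.178 (0.156 to 0.201), and peaks in 3′ and 5′ untranslated regions were close to it with 0.211 (0.140 to 0.301) and 0.253 (0.119 to 0.453). Intron peaks had a ratio of 0.320 (0.303 to 0.338) and distal intergenic peaks one of 0.405 (0.386 to 0.426). Among Control peaks with more than 20 fragments, 75.1% of those within 1 kb of a start site were met (94.8% expected), 64.2% of distal intergenic (93.8%), 48.8% of intron (93.5%) and 29.9% of exon peaks (92.4%).

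**Figure D1:**
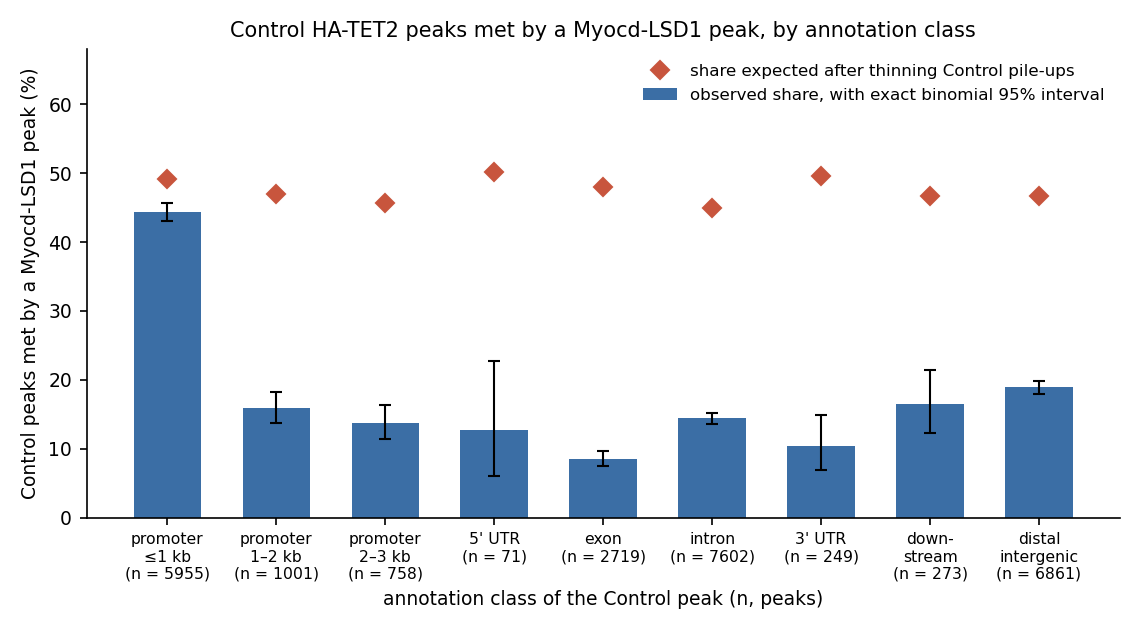
Share of Control peaks met by a Myocd-LSD1 peak (%, vertical axis) for each annotation class of the Control peak (horizontal axis, n is the number of peaks); bars are observed shares with exact binomial 95% intervals and diamonds are the shares expected after thinning Control pile-ups to the Myocd-LSD1 background coverage. Promoter peaks within 1 kb reached 44.4% against 49.1% expected, and exon peaks 8.53% against 48.1%.

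Smooth muscle contractile genes carried HA-TET2 peaks widely in control SMC and at fewer sites in Myocd-LSD1 SMC. Of the 36 genes of this list, 30 had a Control peak and 16 a Myocd-LSD1 peak, all of these 16 among the 30. This share of 53.3% was the same as the random median of 53.3% for matched lists with any assigned peak counted, so the contractile genes did not stand apart in it. Of the TGF-β and BMP list 27 of 30 genes had a Control peak and 18 a Myocd-LSD1 peak, and of the actin cytoskeleton list 31 of 34 and 23. The 14 genes with Control peaks and no Myocd-LSD1 peak included Acta2 (smooth muscle α-actin), Actg2, Csrp1, Des (desmin), Itga5, Itga8, Jph2 (junctophilin), Kcnmb1, Myl9, Nexn, Smtn (smoothelin), Tagln (transgelin) and Tpm1. Acta2 had a Control peak across its start site (rn6 chromosome 1, 252550345 to 252550672, fold 4.79), another in intron 3 of 8 (252544562 to 252544954, fold 5.81) and an intergenic one upstream (252556444 to 252556699, fold 5.55). Each of these rested on 6 or 7 fragments, and the chance of a call after thinning was 0.377 for the promoter peak, so a missing call there says little at this depth. The same holds for Actg2 (0.0473), Itga8 (0.494) and Tagln (0.535) with 1 Control peak each, and for Itga5 and Myl9, whose 2 peaks each gave 0.514 and 0.674 expected calls. Des had a promoter peak of 27 fragments (chromosome 9, 82556553 to 82557215, fold 8.65) whose chance of a call was 0.961. Jph2 had 7 Control peaks on chromosome 3 between 159713371 and 159776558, in the promoter, introns and exons, of which the strongest by fold lay in intron 2 of 5 (159744505 to 159745036, fold 9.08). The strongest Control peak assigned to Nexn lay in an intron of the neighbouring gene Miga1 (chromosome 2, 257502599 to 257503246, fold 14.5).

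Other contractile and adhesion genes had peaks in both lists. Synpo2 (synaptopodin 2) had a met promoter peak (chromosome 2, 227303678 to 227304160, fold 10.2 within the Control list and 10.1 within the Myocd-LSD1 list) and a met peak in intron 4 of 4. Vcl (vinculin) had a met peak across its start site (chromosome 15, 3544722 to 3545013, fold 10.8 and 8.47), and Cald1 (caldesmon) had 1 of 7 Control peaks met, the one across a start site (chromosome 4, 62103878 to 62104211, fold 7.17). Zyx, Pdlim5, Pdlim7 and Ppp1r12b had 1 Control peak each, and each was met. Mylk (myosin light chain kinase) had 5 Control peaks, 1 of them met.

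At the level of peaks, 15 of the 92 Control peaks of the contractile list were met (16.3%, 9.42 to 25.5) and 48.5% were expected after thinning, a ratio of 0.336 (0.194 to 0.525). Of the 66 that lay outside promoters, 6 were met (9.09%). All Control peaks of the same annotation classes and pile-ups were met at 21.1%, which lies within the interval of the list, and against this rate the ratio was 0.771, with an interval from 0.446 to above 1. At promoters, 11 of the 23 contractile genes with a Control peak had a Myocd-LSD1 peak too (47.8%, 26.8 to 69.4), against a median of 43.5% in 10000 random lists matched on peak strength, where the list stood at percentile 61.6. In these libraries the contractile promoters thus did not stand apart from other Control promoters of like strength.

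**Figure D2:**
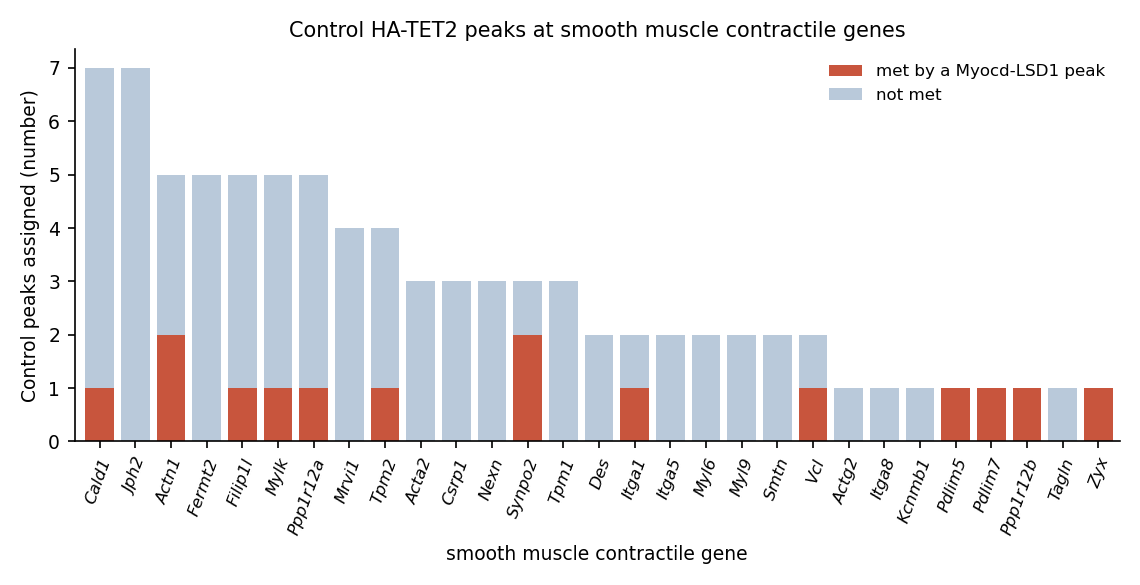
Number of Control peaks (vertical axis) assigned to each smooth muscle contractile gene shown (horizontal axis), split into peaks met by a Myocd-LSD1 peak (red) and not met (pale blue). Actn1 and Synpo2 had 2 met peaks each, and the 7 peaks of Jph2 were not met.

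**Figure D3:**
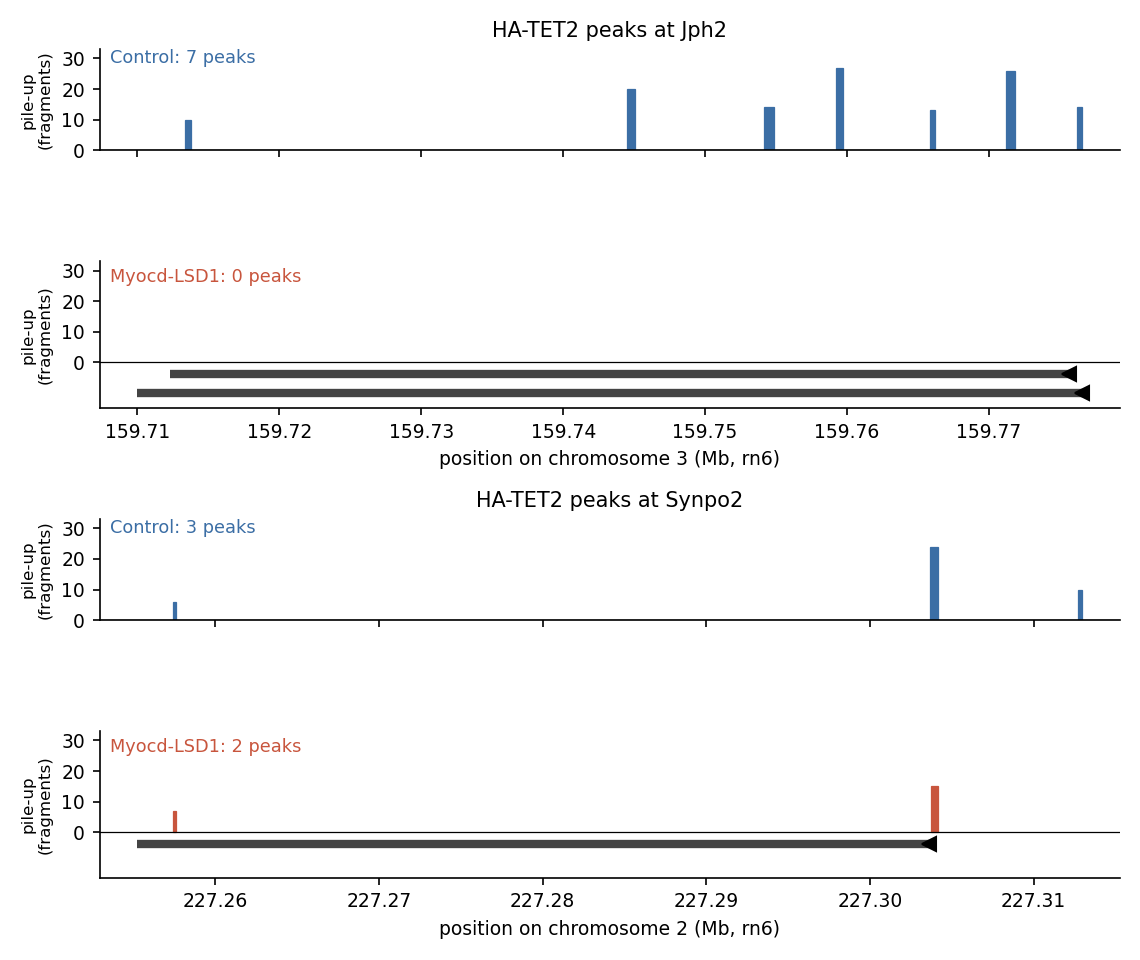
Peaks of both lists at Jph2 and Synpo2, to scale on rn6 (horizontal axes, Mb), with each peak's recovered pile-up in fragments as its height (vertical axes); grey bars are the transcripts to which the peaks were assigned and arrowheads their start sites. Jph2 had 7 Control and 0 Myocd-LSD1 peaks, and Synpo2 had 3 and 2.

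Transcription factors of the smooth muscle programme showed a similar mixture. Of 27 listed factors, 21 had a Control peak and 11 a Myocd-LSD1 peak. Myocd itself had 5 Control peaks and no Myocd-LSD1 peak; the Control peak at its promoter (chromosome 10, 51779148 to 51779319, fold 3.52) rested on 4 fragments. Srf had 2 Control peaks, both in exons of the neighbouring gene Ptk7, and none in Myocd-LSD1. Tead4 had 7 Control peaks, Mef2d 2, and Mef2a, Mkl2 and Yap1 1 each, all without a Myocd-LSD1 peak at the gene. After thinning, 3.47 calls were expected for Tead4 and 1.16 for Myocd. For Srf 0.826 were expected, for Mef2a 0.494, for Mef2d 0.410, for Yap1 0.377 and for Mkl2 0.138. Missing calls at Myocd, Srf, Mef2a, Mef2d, Yap1 and Mkl2 therefore say little at this depth. Smad3 had 11 Control peaks, of which 5 were met, and Mkl1, Smad2, Rbpj and Wwtr1 had promoter peaks in both lists. At promoters 5 of 12 factors had peaks in both lists (41.7%, 15.2 to 72.3), the same as the random median of 41.7%. Under the stricter threshold the share was 16.7% of 6 factors, again equal to its random median.

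The genes that respond early to SRF, and those of the cell cycle and of the actin cytoskeleton, lay in the upper part of the matched random lists without standing apart from them; under the stricter threshold the actin list was at its random median (p = 1 by permutation). Of 12 such genes with a Control promoter peak, 8 also had one in Myocd-LSD1 (66.7%, 34.9 to 90.1; percentile 95.3), among them Fosb (fold 16.5 and 7.20) and Actb. Cell cycle genes had 13 of 20 (65.0%, 40.8 to 84.6; percentile 97.0), with Ccna2, Pcna and E2f3 in both lists and Ccnd1 peaks outside its promoter in Control alone. Actin cytoskeleton and adhesion genes had 13 of 18 (72.2%, 46.5 to 90.3; percentile 93.6), with Rhob and Capn2 in both lists and Lima1 with 5 unmet Control peaks. The housekeeping list had 10 of 15 (66.7%, percentile 79.8), and under the stricter threshold 35.7%, equal to its random median. The TGF-β and BMP list had 9 of 18 (percentile 68.4), with Ski and Bmpr1a in both and Bmp4 in Control alone. Of the H3K4 methylation regulators 6 of 10 had promoter peaks in both lists (percentile 86.7), Kdm1b and Hdac2 among them. Smyd2 and Rcor3, the members of highest Control fold (11.8 and 11.3), had 0 met Control peaks.

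Genes of phenotypic modulation and of DNA methylation did not stand apart either. Phenotypic modulation genes had 4 of 12 (33.3%, 9.92 to 65.1; percentile 39.7), the same as the random median of 33.3%. Lgals3 was in both lists, while Fn1, Klf2 and Mmp9 had Control peaks and no Myocd-LSD1 peak. Among DNA methylation factors 3 of 11 had promoter peaks in both lists (27.3%, 6.02 to 61.0; random median 45.5%, percentile 10.7; with any assigned peak counted, 52.9% against 47.1%), namely the maintenance methyltransferase Dnmt1, Mbd3 and, named outside the fixed rule, the glycosylase Tdg. The 4 Control peaks assigned to the de novo methyltransferase Dnmt3a were unmet, and among them were peaks in introns 12 and 15 of 18 of another gene, Dtnb. An exon peak of Tet3 (exon 9 of 10, chromosome 4, 115105976 to 115106511, fold 12.3) was met. Of 11 homeobox and other fate regulators with a Control promoter peak, only Foxf1 had one in Myocd-LSD1 (9.09%, 0.230 to 41.3), against a random median of 36.4% (percentile 1.3), while with any assigned peak counted 33.3% were in both lists (percentile 9.58). Hoxb5 was the strongest of the others at its promoter (chromosome 10, 84152297 to 84152880, fold 11.2). By permutation of list membership among genes of like peak strength (two-sided), this list alone of the 11 ranked had an unadjusted rank p under 0.05 in this setting (p = 0.0494). In other settings the actin list (0.0266 without matching) and the SRF list (0.0276 under the stricter threshold) also had one, and the homeobox list did not when only peaks within 1 kb were counted (0.0568). In the first setting its Benjamini-Hochberg adjusted p by permutation was 0.508, as was that of the cell cycle list.

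Markers of other cell types carried few promoter peaks, but endothelial markers had assigned peaks of any kind at 13 of 18 genes in Control and 6 in Myocd-LSD1. At promoters, endothelial markers had 3 in Control and 2 of these in Myocd-LSD1, among them Mmrn2. Macrophage and leukocyte markers had 3 and 1, neural genes 2 and 0, skeletal and cardiac muscle genes 4 and 0, and hepatocyte genes 0 in both lists. These 5 lists were too small to rank by promoter peaks; by any assigned peak 4 of them were ranked, and none of these had a rank p under 0.05 by permutation.

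Over all genes, 6946 had a Control promoter peak and 4067 a Myocd-LSD1 promoter peak, with 3014 in both. Thus 43.4% (42.2 to 44.6) of the Control genes were also found in Myocd-LSD1, and 74.1% (72.7 to 75.4) of the Myocd-LSD1 genes in Control. Under the stricter significance minimum the counts were 3921, 1705 and 1320. The strongest promoter peaks found in Control alone belonged to Tmem217, Rgsl1, Mocs3, Psmg3 (a proteasome assembly chaperone), Kbtbd6, Mir7578, Padi3, Cldn4 (a tight junction claudin), Hmgn3 and Zbtb1. Their fold enrichments ran from 12.4 to 14.4 and their pile-ups from 26 to 63 fragments, and the lowest chance of a call after thinning was 98.7%, for Hmgn3. Of these 10 peaks 4 lay across a start site, such as that of Tmem217 (chromosome 20, 8202449 to 8203087), and 8 lay within 1 kb of one. Their median width was 755 bp, against 373.5 bp for the 10 Myocd-LSD1 peaks named next. The strongest found in Myocd-LSD1 alone belonged to Copg1 (a COPI coat subunit), Thop1, Hexim1 (an inhibitor of the elongation factor P-TEFb), Pnrc2, Pex16, Rab14, Max (the dimer partner of Myc), Kif5b, Dcps and Scaf1. They had folds of 7.90 to 11.2 on 9 to 16 fragments, and 9 of the 10 lay across the start site, such as that of Copg1 (chromosome 4, 119814956 to 119815207). The highest-ranked promoter peaks of both lists were those of Vezf1, Evi5l, Kdm4b (a histone H3 lysine 9 demethylase), Gatad2a (a NuRD subunit), Carm1 (an arginine methyltransferase), Rad52, Gpr155, Tsks, Cdca2 and Aco1. The Vezf1 peak (chromosome 10, 75365129 to 75365488 in Control) had the highest fold of each list, 40.6 in Control, and rested on 415 fragments in Control and 201 in Myocd-LSD1. Its local background was also high, with 9.23 fragments in Control and 3.70 in Myocd-LSD1 against uniform backgrounds of 0.175 and 0.0633. The source of this high background was not tested.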

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

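The comparison of exon with intron signal at Tet2 was chosen only after the result was seen; the comparison of peak edges was chosen before, but its set of peaks was widened after. Very high pile-ups stood out at Tet2 itself and on the mitochondrial sequence.

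In both lists 2 Tet2 exons carried very high peaks, at rn6 chromosome 2, 238722435 to 238723834 (exon 1 of 12) and 238744012 to 238746132 (exon 10 of 12, as numbered in the deposited annotation). A Control peak in intron 2 of 11 (238755925 to 238756176) lay at higher coordinates than both exons. Exon 1 in this numbering therefore need not be the first exon of the gene. Their pile-ups were 779 and 1622 fragments in Control and 719 and 1474 in Myocd-LSD1, so that relative to background coverage they were 2.55 and 2.51 times as high in Myocd-LSD1 as in Control. The lower of the Control exon pile-ups was 129.8 times the only other Control peak in the gene, an intron peak of 6 fragments, as DNA of the TET2 coding sequence carried by the adenovirus would give, and such DNA is a candidate source. Binding of TET2 at its own gene was not excluded: the peak edges differed by 0 to 2 bp between the lists, and of 45 other strong shared peaks 4 (8.89%) had edges as close, 3 of them over a local background above 10 fragments; over the 30 of these peaks whose pile-ups were solved within rounding, the set first used, 0 did, a result that spoke against binding. The set was widened after that result was seen, because the first way of solving pile-ups left out strong peaks, 3 of the 4 Tet2 exon peaks included, so that the comparison decides nothing.

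The mitochondrial sequence had 9 Control and 11 Myocd-LSD1 peaks, of which 7 and 8 had a recovered pile-up; among these the highest pile-up over background coverage was 1.36 times as high in Myocd-LSD1 as in Control. No biological explanation of the differences between the lists at Tet2 or on the mitochondrial sequence was tested.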

How the results depend on the processing

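The settings with a minimum pile-up, without high-background peaks, with the second scaling and with peaks of the same class were chosen after seeing the data; the others were planned. No paired analysis was possible because each group had 1 list, and for the same reason no replicate could be left out. Retention of the 11 ranked gene lists stayed on the same side of the adjusted threshold in all 69 recomputed values; for the contractile list it ran from 47.8% to 63.6%, with adjusted p from 0.903 to 1, for the actin list up to 80.0% (equal to its random median under the stricter threshold), for the SRF list from 57.1% to 85.7% and for the homeobox list from 9.09% to 33.3%. A share, or a ratio of observed to expected share, counted as moved when it left the interval of the first setting, and a count or the ratio of peak numbers when it differed by over 1.5 times. By this measure no value moved with assembled chromosomes alone, nor did the number of peaks with touching peaks merged, nor the overlap without mitochondrial, Tet2 and high-background peaks. The promoter share stayed higher and the exon share lower in Myocd-LSD1 in each setting run. Under the stricter threshold the peak ratio was 4.28, 18.3% of Control and 78.7% of Myocd-LSD1 peaks were met, promoters held 32.0% and 57.5%, exons 11.1% and 2.71%, peaks within 1 kb of a start site 25.2% and 53.2%, and promoter genes numbered 3921, 1705 and 1320 in both. With equal numbers of peaks the ratio was 1 by construction, 38.7% and 39.1% were met, Control promoters held 32.7%, exons 11.3% and peaks within 1 kb 25.8%, and promoter genes numbered 2977 in Control and 1833 in both. A reciprocal overlap of 50% gave 14.4% and 38.6%, and a window of 1 kb 24.4% and 63.7%, since the rule itself is narrower or wider. Counting any peak of a gene gave 13312, 7579 and 6151 genes. The lowest decile of Control peaks was met at 5.13% when ranked by significance and 8.31% by width, and the highest decile by width at 44.8%. With pile-ups of at least 5, 19.7% and 78.6% were met, promoters held 31.5% and 55.0%, and exons 11.3% and 2.90%. Thinning to the pile-up ratio at 474 strong shared peaks (0.257) gave ratios of observed to expected share of 1.18 for promoters within 1 kb, 0.233 for exons, 0.423 for introns and 0.526 for distal intergenic sites; against peaks of the same class and pile-up the contractile list had 0.771. Apart from the settings that fix the number or the rule, the cause was not tested. Depth limits the weak sites: 30.2% of Myocd-LSD1 peaks had 3 fragments or fewer.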

Other observations

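The tests of coverage, of pile-up and of the cell line below were chosen only after the result was seen; those of copy number and of spliced RNA were chosen before. Exon peaks were spread over many genes. The 2723 Control exon peaks lay in 2251 genes, 64 of which had at least 3, and the 333 of Myocd-LSD1 in 323 genes. Dst and Wdfy3 had 9 Control exon peaks each, Lrp1 (an endocytic receptor) 8, and Lama5 (a laminin chain) and Nav2 7 each, and none of these was met. The unmet exon peaks with the most fragments, a ranking by pile-up and not by fold, lay in Usp19 (exon 23 of 27, chromosome 8, 117288893 to 117289760, 80 fragments), Apc2 (76 fragments), Klhl26 (75) and Pxdn (69).

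Peaks on chromosome X were few in both lists, with 173 in Control (0.679% of peaks on assembled chromosomes) and 99 in Myocd-LSD1 (1.04%), while the chromosome makes up 5.76% of the length spanned by peaks. Chromosomes 12 and 20 held larger shares of the Control list than of the Myocd-LSD1 list, by ratios of 1.26 and 1.25.

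Lower coverage of the Myocd-LSD1 library may account for most unmet promoter peaks within 1 kb of a start site, where the share met was 0.904 of that expected after thinning, although it was 0.792 of it (0.745 to 0.836) for those with more than 20 fragments and 1.18 when thinning followed strong shared peaks. Coverage alone also leaves many peaks of the other classes unmet, but not as many as were counted: the share met was 0.178 of that expected for exon, 0.320 for intron and 0.405 for distal intergenic peaks. Exon peaks did not have lower pile-ups than those promoter peaks (medians 9 and 8). Reweighting them to the promoter pile-ups (0.145 times the promoter share) therefore adds nothing. The highest ratio of observed to expected exon share on any of the 20 autosomes was 0.272. The low exon share was thus not confined to a few autosomes, which argues against copy number of whole autosomes as its cause. Gains or losses of parts of an autosome could not show in this comparison. Of the housekeeping genes, 6.25% had a Control exon peak. The exon class leaves out exons within promoters, so a peak over an exon near a start site could not count. That percentage therefore does not decide whether spliced RNA contributed. An effect of the Myocd-LSD1 line cannot be told apart from a difference between libraries, with 1 list per group. Whether the Control list, named by 2 samples, came from pooled reads is not known. A weaker antibody signal over transposase cutting at open promoters, and GC content, were not tested and stay open.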
